A study of Homo sapiens with 63 samples.

How the data were processed

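Transcripts were measured by RNA-seq in human eosinophils and mast cells cultured with IL-4, IL-13, IL-33 or no cytokine. Per the series' design text, eosinophils were isolated from buffy coats by magnetic depletion. Mast cells were differentiated from CD133-positive bone marrow cells with IL-6 at 50 ng/mL, SCF at 100 ng/mL and IL-3 at 1 ng/mL for 3 weeks, then with IL-6 and SCF for 4 weeks. The tissue label of the mast cell samples reads blood, while the design text gives bone marrow. Cells were kept in RPMI with 10% serum and cytokines were given at 100 nM, overnight for eosinophils and for 48 hours for mast cells. Per the labels' protocols, stranded mRNA libraries were made from 500 ng of RNA with 12 PCR cycles and sequenced as single reads of 33 cycles. No molecular identifiers are described, so intervals and floors cover counting error only.

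The values are estimated counts per gene, not normalized, deposited by the authors in 1 table per cell type. The submitters' processing notes name the build GRCh37. The aligner, the counting method, the gene annotation and the use of strand are not given in the sources used here. Of all values, zeros included, 69.8% in eosinophils and 82.3% in mast cells were whole within 0.0001, so they were treated as estimated counts. Each table had 30373 genes, of which 1354 carried a symbol with a copy number and 82 that could tell a person's sex were left out of totals and fits. The reference at hand was of another build, so no coordinates are given. Genes with close copies, and genes that overlap on the opposite strand, are uncertain.

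Counts were rounded after summing the libraries of each donor and treatment. This gave 8 sums from 24 eosinophil libraries, 3 per donor and treatment, and 20 sums from 39 mast cell libraries, 2 per donor and treatment with 1 for the untreated cells of 1 donor. What separates the libraries of 1 donor and treatment is not given in the sources used here. Their counts differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 2.04 to 90.36 (median 6.84) in eosinophils and 1.78 to 7.12 (median 2.45) in mast cells, over genes with at least 20 summed counts. The donor is the replicate, except in the alternatives said to take libraries as samples. Library totals were 5.2 to 21.4 M counts in eosinophils and 10.7 to 17.9 M in 38 mast cell libraries, with 201.5 M in 1 untreated mast cell library.

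The design, gene lists, naming rule and alternatives were set before the data were examined, except those said to be chosen after seeing the data. Each cell type was fitted with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default low-count filter, the robust quasi-likelihood F test and a model of treatment plus donor. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All 4 treatments entered each fit so that they shared 1 estimate of the spread. The standard error is the absolute log2 fold change divided by the square root of F. The pairing comes from the same donor giving cells to all 4 treatments. Deviations from the treatment means in mast cells correlated at -0.02 to 0.92 (median 0.62) between sums of the same donor. Between sums of different donors they correlated at -0.78 to 0.7 (median -0.14), so the ranges overlap. With 2 donors in eosinophils the deviations mirror each other, so the check is void there. Differences between cell types were tested as the interaction of treatment and cell type over 28 sums.

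Named genes were, for each cytokine against no cytokine, up to 8 with the largest increase and 8 with the largest decrease, and 4 and 4 for direct comparisons and for differences between cell types. They had an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, the same direction in every donor and a gene symbol that is no placeholder. Up to 4 members of lowest p per gene list were added, and IL1RL1, IL4R, IL13RA1, IL2RG and CISH were always named. Some genes that this rule names are not reported here. The 21 lists covered STAT6 and NF-kB targets, chemokines, cytokines, cytokine receptors, mast cell granules, IgE receptor signalling, eicosanoids, eosinophil identity, adhesion and activation, MHC class II, interferon response, survival, cell cycle and glycolysis. Further lists held markers of neutrophils, T and NK cells, B cells, monocytes, erythroid cells and platelets, and progenitors. Of the genes in the lists 19 stand in more than 1. Lists with at least 5 measured members were tested with limma 3.58.1 camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group's libraries. With 1 to 3 counts it is a ratio of pooled CPM with an exact 95% interval.

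Alternatives were RLE, upper quartile and library total scaling, no low-count filter and a filter at 5 CPM, DESeq2 1.42.0, limma-voom, no replicate block, every library as a sample, fits of only the 2 treatments compared, and each donor or library left out. Chosen after seeing the data were a fit without 2 mast cell donors and a fit with the deepest library thinned to the median total of the others. The donors were left out because CISH in their libraries labelled IL-4 was under 2 times their untreated level. No library was moved to another label. For IL-4 against IL-13 in eosinophils, each further library was also left out of the fits without the IL-13 libraries 1-7, 1-8 and 1-9. With 1 eosinophil donor left out, the libraries of the other donor served as samples. The eosinophil fits of only the 2 treatments compared took every library as a sample too.

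The fits were tested on simulated counts with changed genes added. These were drawn from genes of higher counts and changed alike in every donor. In the mast cells as labelled, 2 of 5 donors did not share the responses of the others. Recovery there is thus no measure of the power for genes that changed in only some donors. For IL-33 in mast cells of 5 donors, 47.8%, 68.7% and 90.9% of genes changed 1.5-, 2- and 4-fold were recovered among 14713 genes, with 4 calls among the unchanged. Without the 2 donors these were 70.1%, 89.6% and 98.5% of the changed genes among 14481, with 16 such calls. In eosinophils 43.3%, 80.6% and 93.9% were recovered among 17258, with 19 such calls. Of 67, 67 and 66 changed genes, 47, 60 and 65 were recovered without the 2 donors and 29, 54 and 62 in eosinophils. Set against these numbers, the 16 and 19 calls among the unchanged made up a larger share of calls than the threshold sets. Calls in these fits may thus hold more false ones than the threshold states. For the difference between cell types 1.6%, 40.6% and 75.8% were recovered among 14444, with 0 such calls. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.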

Results

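RNA was sequenced from 2 human cell types exposed to single cytokines in culture. Eosinophils, granulocytes of allergic inflammation, came from the blood of 2 donors and were cultured overnight. Mast cells, tissue cells that release histamine and proteases, were grown from bone marrow progenitors of 5 donors and were treated for 48 hours. Each donor's cells received IL-4, IL-13 or IL-33 at 100 nM, or no cytokine. IL-4 and IL-13 share the receptor chain IL4R, the target of the antibody dupilumab. IL-33, the target of the antibody itepekimab, binds the receptor encoded by IL1RL1. Both antibodies are named in the title of the series. The 24 eosinophil libraries made 8 sums per donor and treatment, and the 39 mast cell libraries made 20. Eosinophil libraries held 5.2 to 21.4 M counts (M, mega). The 6 with IL-4 held 17.6 to 21.4 M and all others at most 16.4 M, so numbers of calls are not compared at equal depth. Mast cell libraries held 10.7 to 17.9 M counts, apart from 1 untreated library of 201.5 M. Changes below are log2 fold changes ± standard error, and levels are CPM, mean ± SD over donors, with n = 2 donors for eosinophils. Genes are given by symbol as in the count tables, without coordinates. Eosinophil libraries are named by treatment, donor and number.

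CISH, an inhibitor of cytokine signalling that IL-4 raises in many blood cells, served as a check of the labels. It rose in both eosinophil donors with each cytokine. In 2 of the 5 mast cell donors, CISH in the libraries labelled IL-4 did not reach 2-fold of the untreated level. These libraries did not pass this check. The only untreated library of 1 of these donors was that of 201.5 M counts. In these 2 donors BIRC3, an inhibitor of apoptosis and target of NF-kB, stood at 0.05 and 0.93 times the untreated level in libraries labelled IL-33, against 90.2 to 101 times in the other 3. The summed NF-kB targets reached 2380 CPM in untreated libraries of all 5 donors and at most 732 CPM in the other 3. The calls of every mast cell comparison are first given for all 5 donors as labelled. They are then given without those 2 donors, an alternative chosen after seeing the data. That choice rests on a measured response in libraries labelled IL-4, so the counts and p-values of the 3 remaining donors are conditional on it. CISH and other IL-4 response genes are then no independent evidence of an IL-4 effect.

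Eosinophils treated with IL-4 were compared with untreated eosinophils to find which transcripts the cytokine changed. CCL26, encoding the eosinophil attractant eotaxin-3, went from 3 counts over the 6 untreated libraries to 2724 counts, a ratio of 583 in CPM (95% counting interval 199 to 2827, adjusted p = 1.27e-10). CCL17, another CC chemokine, rose by 8.10 ± 0.32 (adjusted p = 6.85e-11), to 20.1 ± 13.5 CPM. MAOA, which encodes monoamine oxidase A, rose by 6.22 ± 0.36, from 0.239 ± 0.0961 to 17.8 ± 3.10 CPM (adjusted p = 9.93e-08). IL17RB, a receptor chain for IL-25, rose by 5.99 ± 0.73 (adjusted p = 0.0248). GGT5, GOLM1, MAL and F13A1, the coagulation factor XIII A chain, rose by 7.15 ± 0.65, 5.96 ± 0.22, 5.49 ± 0.37 and 4.46 ± 0.27. GGT5 has close relatives that could share its reads. The largest decreases were smaller. CD300E fell by 2.92 ± 0.26, VMO1 by 2.48 ± 0.46, TNS1 by 2.00 ± 0.23 and THBS1, thrombospondin-1, by 1.91 ± 0.24. PNMA6C fell by 1.85 ± 0.23, CD14, a monocyte co-receptor for lipopolysaccharide, by 1.83 ± 0.17, SLCO4A1 by 1.72 ± 0.21 and TGM3 by 1.71 ± 0.23.

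Of the 20 measured targets of STAT6, the transcription factor activated by IL-4 and IL-13, 17 rose and 0 fell in eosinophils with IL-4. All 20 rose when adjusted over the list alone. The list test gave an adjusted p of 5.80e-30 with a preset correlation and 0.212 with an estimated correlation. FCER2, the low-affinity IgE receptor, rose by 4.35 ± 0.19 and BCL6, a transcriptional repressor, by 1.93 ± 0.14. CISH rose by 4.09 ± 0.21, from 6.63 ± 0.982 to 116 ± 18.4 CPM (adjusted p = 1.84e-07). Among 19 chemokines, 7 rose and 3 fell (8 and 4 adjusted over the list alone; list adjusted p = 0.00372, and 0.5 with an estimated correlation). CCL13 and CCL24 rose by 5.72 ± 0.50 and 2.50 ± 0.31, while CCL2 fell by 1.61 ± 0.21. Of 12 genes for antigen presentation by MHC class II, 6 rose and 0 fell (7 and 1 adjusted over the list alone; list adjusted p = 0.000735, and 0.5 with an estimated correlation). CIITA, the master regulator of these genes, rose by 2.02 ± 0.14 and HLA-DRA by 1.41 ± 0.14. HLA genes vary between people and share sequence, so their counts are uncertain.

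Surface receptors also changed with IL-4. Of 23 cytokine receptor chains 9 rose and 2 fell (10 and 4 adjusted over the list alone; list adjusted p = 0.0284, and 0.703 with an estimated correlation). IL1RL1, the IL-33 receptor, rose by 1.58 ± 0.14, to 185 ± 133 CPM from 57.7 ± 37.3 (adjusted p = 9.50e-07). IL1R1 rose by 1.57 ± 0.18 and IL3RA by 1.13 ± 0.16, and TNFRSF1B, a receptor for TNF, fell by 0.96 ± 0.14. IL4R rose by 0.56 ± 0.13 (adjusted p = 0.0102). IL13RA1 and IL2RG did not pass the test, with changes of -0.14 ± 0.13 and 0.09 ± 0.13 and adjusted p of 0.632 and 0.774. Of 20 adhesion and activation genes 8 rose and 1 fell (9 and 2 adjusted over the list alone; list adjusted p = 0.0034, and 0.703 with an estimated correlation). ICAM1, an adhesion molecule, rose by 1.73 ± 0.19, and CXCR4, the receptor for CXCL12, fell by 1.30 ± 0.13. HRH4, the histamine H4 receptor, rose by 2.24 ± 0.15, and RNASE3, eosinophil cationic protein, fell by 0.84 ± 0.13. Within the eosinophil identity list 1 of 18 rose and 3 fell (5 and 8 adjusted over the list alone), with a list adjusted p of 0.491.

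Markers of other blood cells moved with IL-4 in the same libraries. Of 11 neutrophil markers 1 rose and 5 fell (1 and 7 adjusted over the list alone; list adjusted p = 0.00049, and 0.272 with an estimated correlation). CAMP and FCGR3B fell by 1.64 ± 0.14 and 1.14 ± 0.15, while MME rose by 1.28 ± 0.23. Of 10 monocyte and macrophage markers 1 rose and 5 fell (1 and 6 adjusted over the list alone; list adjusted p = 0.0014, and 0.48 with an estimated correlation). CD163 fell by 1.49 ± 0.25 and FCN1 by 0.67 ± 0.13, while FCGR1A rose by 0.98 ± 0.21. The summed level of the monocyte markers was 616 ± 91.1 CPM with IL-4 and 899 ± 37.6 CPM without cytokine. Neutrophil markers summed to 6980 ± 4160 and 8460 ± 4120 CPM, and the eosinophil identity genes to 6860 ± 96.2 and 6330 ± 961 CPM. Untreated, the neutrophil sum was 5550 and 11400 CPM in the 2 donors. With IL-13 and IL-33 it was 8060 ± 4540 and 6690 ± 3950 CPM. All changes given for eosinophils are thus those of the whole preparation, whose share of neutrophils was not measured. Of 18 interferon-stimulated genes 1 fell (4 adjusted over the list alone), with a median of -0.82 and a list adjusted p of 1.24e-05, or 0.703 with an estimated correlation. The list tests of NF-kB targets (1 rose, 3 fell), cytokines (2 rose), mast cell granule genes (3 fell), IgE receptor signalling (2 rose) and eicosanoid genes (1 rose, 3 fell) did not pass, with adjusted p of 0.665, 0.88, 0.246, 0.862 and 0.854. Adjusted over the list alone, 3, 2, 2, 2 and 2 rose and 6, 0, 5, 1 and 3 fell. Those of survival (2 rose, 1 fell), cell cycle (1 rose, 1 fell), glycolysis (1 rose), T and NK cell (0) and B cell genes (1 rose, 1 fell) gave adjusted p of 0.968, 0.207, 0.959, 0.959 and 0.458. Adjusted over the list alone, 4, 2, 1, 1 and 1 of them rose and 3, 1, 0, 0 and 3 fell. Erythroid and platelet markers (0, and 0 adjusted over the list alone) and progenitor markers (1 rose and 1 fell, or 1 and 3 adjusted over the list alone) gave 0.491 and 0.294. Over all 17666 genes tested, edgeR called 1086 with IL-4, 705 higher and 381 lower. Without the donor as a replicate block edgeR called 0, with 602 at an unadjusted p under 0.05. Without the IL-13 library 1-8 the count was 720, and with either donor left out 558 to 5218.

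IL-13 was compared with no cytokine in the same eosinophil donors. CCL26 again went from 3 untreated counts to 1045, a CPM ratio of 383 (95% counting interval 131 to 1862), and CCL17 rose by 8.39 ± 0.32, to 23.3 ± 13.2 CPM (adjusted p = 7.50e-11). GGT5 rose by 7.02 ± 0.65, MAOA by 5.51 ± 0.36, GOLM1 by 4.61 ± 0.21, FCER2 by 4.26 ± 0.19, F13A1 by 4.14 ± 0.27 and ZNF703 by 3.88 ± 0.25. CD300E fell by 2.15 ± 0.26, THBS1 by 1.84 ± 0.24, CCL2 by 1.60 ± 0.22, RNASE6 by 1.56 ± 0.19 and TNS1 by 1.56 ± 0.23. CD14, SLCO4A1 and LGMN, a lysosomal protease, fell by 1.53 ± 0.17, 1.44 ± 0.22 and 1.40 ± 0.23. Of 20 STAT6 targets 15 rose (18 adjusted over the list alone; list adjusted p = 7.12e-36, and 0.164 with an estimated correlation), among them CISH by 3.61 ± 0.21, to 83.0 ± 1.52 CPM. Of the MHC class II genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; list adjusted p = 6.95e-05, and 0.575 with an estimated correlation), with CIITA up by 1.68 ± 0.14 and HLA-DRA by 1.18 ± 0.14. ICAM1 rose by 1.42 ± 0.19 and CXCR4 fell by 1.07 ± 0.13, 2 of the 6 changed adhesion and activation genes.

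Of the receptors, IL1RL1 rose with IL-13 by 1.09 ± 0.14 (adjusted p = 0.000114) and HRH4 by 1.64 ± 0.15. The chains of the IL-13 receptor, IL4R and IL13RA1, did not pass the test, at 0.24 ± 0.13 (adjusted p = 0.543) and -0.36 ± 0.14 (adjusted p = 0.274). Neither did IL2RG, a chain of other cytokine receptors, at -0.04 ± 0.13 (adjusted p = 0.954). LTC4S, the synthase of cysteinyl leukotrienes, rose by 0.80 ± 0.14, and PTGER4, a prostaglandin E2 receptor, fell by 0.90 ± 0.14. Monocyte markers moved here too: 4 of 10 fell (4 adjusted over the list alone; list adjusted p = 0.000322, and 0.553 with an estimated correlation), among them CD163 by 1.39 ± 0.25. None of the interferon-stimulated genes passed over all genes and 5 fell adjusted over the list alone (list adjusted p = 9.67e-07, and 0.646 with an estimated correlation). The adhesion and cell cycle lists each gave 0.0444, and 0.646 with an estimated correlation. The other 15 lists did not pass. With IL-13, edgeR called 413 genes, 289 higher and 124 lower. Without the replicate block it called 0, with 367 at an unadjusted p under 0.05, and with either donor left out it was 200 to 1563.

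IL-33 was compared with no cytokine in the same eosinophils. COL13A1, a transmembrane collagen, rose by 9.09 ± 0.81, from 0.537 ± 0.693 to 248 ± 72.6 CPM (adjusted p = 0.0105). KCNN1, a potassium channel, rose by 8.92 ± 0.85 (adjusted p = 0.00806). FFAR1, a fatty acid receptor, and SLC18A1, a vesicular amine transporter, went from 2 and 3 untreated counts to 637 and 569, CPM ratios of 294 (81.2 to 2437) and 175 (59.7 to 853). KCNH4 rose by 6.59 ± 0.36, GGT5 by 6.17 ± 0.64, CCL4 by 6.13 ± 0.20 and PPM1N by 6.11 ± 0.28. MIAT, a long noncoding RNA, fell by 2.46 ± 0.13, from 217 ± 16.4 to 38.4 ± 6.16 CPM (adjusted p = 8.14e-10). CNTNAP3B fell by 2.07 ± 0.24, OXER1, a receptor for oxo-eicosanoids that attract eosinophils, by 2.05 ± 0.22, PDZD3 by 1.97 ± 0.30 and PCDH8 by 1.95 ± 0.30. CCDC153, CENPV and IL34 fell by 1.78 ± 0.23, 1.77 ± 0.23 and 1.71 ± 0.28.

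Of 20 targets of NF-kB, the pathway downstream of the IL-33 receptor, 18 rose and 0 fell in eosinophils with IL-33 (19 and 0 adjusted over the list alone; list adjusted p = 2.14e-21, and 0.411 with an estimated correlation). NFKB2 rose by 3.23 ± 0.14, TNFAIP3 by 3.55 ± 0.15 and NFKBIA, the inhibitor of NF-kB, by 3.08 ± 0.15, to 1100 ± 63.9 CPM. BIRC3 rose by 4.44 ± 0.34. Of 17 survival genes 9 rose (9 adjusted over the list alone; list adjusted p = 0.000376, and 0.411 with an estimated correlation), including PIM2 by 2.44 ± 0.13 and BCL2L1 by 2.28 ± 0.15. Of 19 chemokines 6 rose (7 adjusted over the list alone; list adjusted p = 0.00272, and 0.411 with an estimated correlation). CCL3 rose by 5.26 ± 0.17, CCL24, eotaxin-2, by 5.88 ± 0.30 and CCL23 by 3.56 ± 0.28. CCL3 and CCL4 have near-identical copies, so their counts are uncertain. Of 23 cytokines 7 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.0449, and 0.411 with an estimated correlation). IL1A rose by 3.14 ± 0.26 and IL1B by 2.83 ± 0.15. IL5, a survival factor of eosinophils, had 0 untreated counts and 50 with IL-33, at least 15.4-fold higher by a floor of 3 counts over the group, at 0.578 ± 0.187 CPM.

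Receptor chains changed widely with IL-33: 11 of 23 rose and 3 fell (12 and 3 adjusted over the list alone; list adjusted p = 0.00117, and 0.426 with an estimated correlation). IL10RA rose by 3.31 ± 0.14. IL2RG rose by 1.89 ± 0.14 (adjusted p = 3.61e-08), IL13RA1 by 1.77 ± 0.14 (adjusted p = 9.40e-08) and IL1RL1 by 1.00 ± 0.14 (adjusted p = 6.18e-05), while IL4R was at 0.13 ± 0.12 (adjusted p = 0.643). IL5RA, the IL-5 receptor chain that marks eosinophils, fell by 1.03 ± 0.12. The eosinophil identity list went both ways, with 4 up and 5 down of 18 (5 and 7 adjusted over the list alone; list adjusted p = 0.32). CLC, the Charcot-Leyden crystal protein, fell by 1.44 ± 0.14 and CEBPE, a granulocyte transcription factor, by 1.28 ± 0.15. SMPD3 rose by 2.12 ± 0.15 and EMR1, an adhesion receptor of eosinophils, by 1.11 ± 0.13. ICAM1 rose by 3.25 ± 0.20, and of 20 adhesion and activation genes 8 rose and 2 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.00417, and 0.458 with an estimated correlation).

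Of 20 STAT6 targets 7 rose with IL-33 (9 adjusted over the list alone; list adjusted p = 0.000376, and 0.411 with an estimated correlation), among them CISH by 2.04 ± 0.20, MRC1 by 2.44 ± 0.21 and BCL6 by 1.25 ± 0.13. Among the eicosanoid genes 4 rose and 5 fell (5 and 5 adjusted over the list alone; list adjusted p = 0.97); PTGER2 rose by 1.98 ± 0.18, and ALOX5 and LTC4S, enzymes of leukotriene synthesis, fell by 1.00 ± 0.17 and 0.94 ± 0.15. Progenitor markers (4 of 10 fell, list adjusted p = 0.00272), T and NK cell markers (2 of 12 fell, 0.0227), monocyte markers (2 of 10 fell, 0.0364) and neutrophil markers (3 of 11 fell, 0.0449) were lower in these libraries. With an estimated correlation these gave adjusted p of 0.411, 0.426, 0.411 and 0.411, and adjusted over the list alone 5, 2, 4 and 5 fell. With IL-33 edgeR called 1864 genes, 1096 higher and 768 lower. Upper quartile scaling gave 962 higher and 1015 lower. Without the replicate block the count was 59, and with either donor left out 779 to 6390.

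**Figure D1:**
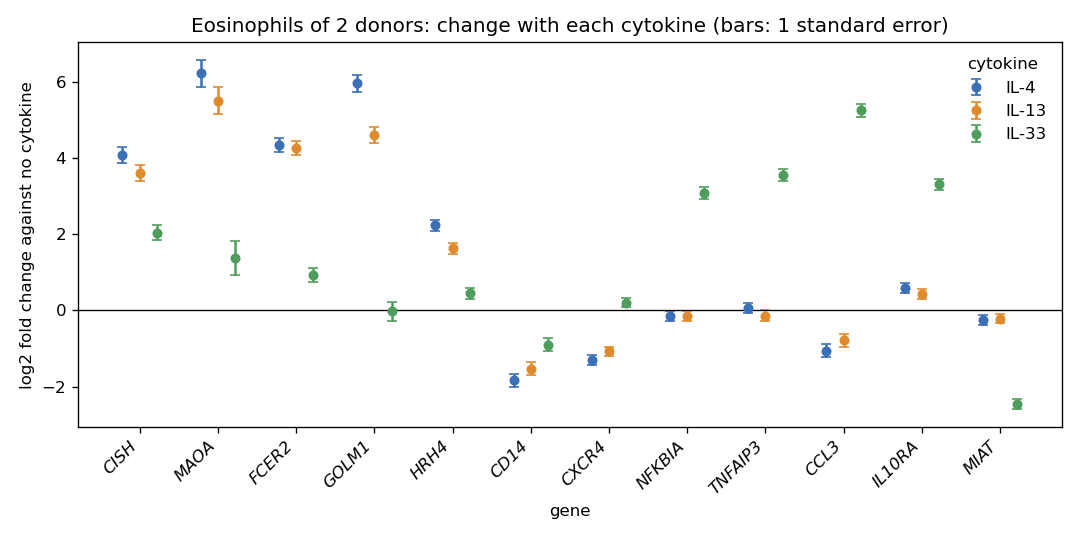
Log2 fold change against untreated eosinophils (vertical axis) of 12 genes with IL-4, IL-13 and IL-33, from the edgeR fit over 2 donors, with bars of 1 standard error. MAOA, GOLM1, FCER2 and CISH stood above 3 with IL-4 and IL-13, NFKBIA, TNFAIP3, CCL3 and IL10RA stood above 3 with IL-33, and CD14 was below 0 with each of the 3 cytokines.

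In mast cells of all 5 donors as labelled, IL-33 was compared with no cytokine. HLA-DRB1, a chain of MHC class II, rose by 1.81 ± 0.26 (edgeR adjusted p = 0.031), from 12.0 ± 9.94 to 65.5 ± 96.2 CPM, and HLA-DQA1 by 1.49 ± 0.21 (adjusted p = 0.031). IL10RA rose by 1.46 ± 0.22, MAP3K8, a kinase of inflammatory signalling, by 1.49 ± 0.25, and NR4A3, an orphan nuclear receptor, by 1.27 ± 0.21. CTNNAL1 and CORO2A rose by 1.57 ± 0.26 and 1.41 ± 0.24. MCU, the mitochondrial calcium uniporter, fell by 0.44 ± 0.07 (adjusted p = 0.0344). IL2RG was at 2.03 ± 0.52 (adjusted p = 0.0602), CISH at 0.76 ± 0.53 (adjusted p = 0.416), IL1RL1 at 0.36 ± 0.44 (adjusted p = 0.663), IL4R at 0.29 ± 0.22 (adjusted p = 0.457) and IL13RA1 at 0.06 ± 0.43 (adjusted p = 0.949). Of 20 NF-kB targets 0 passed over all genes and 15 rose adjusted over the list alone (list adjusted p = 1.02e-07, and 0.312 with an estimated correlation). Of 12 MHC class II genes 2 rose over all genes and 10 adjusted over the list alone (4.63e-09, and 0.312 with an estimated correlation). STAT6 targets (7 rose adjusted over the list alone), chemokines (8 rose, 2 fell), receptors (6 rose), progenitor markers (6 rose) and monocyte markers (1 rose) had list adjusted p of 3.26e-06, 0.00432, 0.00573, 1.09e-05 and 0.041. IgE receptor signalling genes were lower (4 fell adjusted over the list alone; list adjusted p = 0.0191). With an estimated correlation these 6 lists gave 0.312, 0.312, 0.312, 0.312, 0.563 and 0.326. The summed MHC class II genes stood at 1530 ± 2430 CPM with IL-33 (n = 5 donors, at most 5870), and in the same libraries monocyte markers at 651 ± 857 (at most 2180), neutrophil markers at 298 ± 373 (at most 962) and T and NK cell markers at 46.4 ± 65.5 (at most 163). Progenitor markers stood at 1790 ± 1590 CPM (at most 4550, and 1760 in the 3 donors that passed the CISH check).

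Of 15003 genes tested in the 5 donors edgeR called 14 with IL-33, 11 higher and 3 lower, and 3429 had an unadjusted p under 0.05. DESeq2 called 1580 and limma-voom 106. Without the replicate block edgeR called 0, with 1300 at an unadjusted p under 0.05. With a donor left out the count was 0 to 3503. Leaving out a single library moved it by over 1.5 times for 11 of the 39 libraries, within 9 to 593. Thinning the deepest library gave 159. Without the 2 donors that did not pass the CISH check, 6473 of 14833 genes were called, 3124 higher and 3349 lower.

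In those 3 donors the type 2 cytokine genes IL13 and IL5 were counted in mast cells with IL-33 and not in untreated cells, where the floor was 0.0348 CPM. IL13 had 0 untreated counts and 2185 with IL-33, at least 711-fold higher by the same floor, at 24.7 ± 17.6 CPM (n = 3 donors). IL5 was at least 136-fold higher and EBI3, a cytokine subunit, at least 713-fold. Untreated cells of all 5 donors, with the library of 201.5 M, held 18 IL13 and 13 IL5 counts. CSF2, which encodes GM-CSF, went from 2 to 821 counts, a CPM ratio of 401 (111 to 3317), and the chemokine CCL13 from 2 to 674, a ratio of 329 (90.8 to 2724). MUC4, a mucin, was at least 261-fold higher, and FCRL5, CDH13 and KCNK13, with 1 untreated count each, had ratios of 952 (171 to 37658), 887 (159 to 35073) and 437 (78.0 to 17286). BIRC3 rose by 6.57 ± 0.09, TNFRSF9 by 7.35 ± 0.19, TNF by 5.21 ± 0.28 and PTGS2, cyclooxygenase-2, by 3.67 ± 0.27. Of 20 NF-kB targets 19 rose (19 adjusted over the list alone; list adjusted p = 1.84e-15, and 0.0286 with an estimated correlation). Of 23 receptor chains 15 rose and 3 fell (17 and 3 adjusted over the list alone; 2.36e-05, and 0.0286 with an estimated correlation), with IL2RG up by 2.99 ± 0.12, IL1RL1 by 1.35 ± 0.07 and IL4R by 0.72 ± 0.04. IL13RA1 was at -0.27 ± 0.23 (adjusted p = 0.376), and CISH rose by 0.81 ± 0.14.

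MAS1L, TRIM63, JPH4 and FREM1 fell with IL-33 in the 3 donors by 3.43 ± 0.26, 3.40 ± 0.29, 3.38 ± 0.15 and 3.33 ± 0.11. DGCR5, PADI2, NTM and ANXA8 fell by 3.30 ± 0.16, 3.25 ± 0.25, 3.16 ± 0.28 and 3.15 ± 0.21. Of 18 genes of IgE receptor signalling 5 rose and 11 fell (5 and 12 adjusted over the list alone; list adjusted p = 0.02, and 0.24 with an estimated correlation), including the inhibitory receptor SIGLEC8 by 2.62 ± 0.13. The granule proteases CMA1, chymase, and CTSG, cathepsin G, fell by 1.64 ± 0.07 and 2.47 ± 0.18, while HDC, the histamine-forming enzyme, rose by 0.93 ± 0.06. Granule genes as a list went both ways, with 3 up and 5 down of 15 (3 and 5 adjusted over the list alone; list adjusted p = 0.505). Progenitor markers moved with these changes: 6 of 9 rose (6 adjusted over the list alone; list adjusted p = 0.000546, and 0.187 with an estimated correlation), including MPO by 2.29 ± 0.14 and ELANE by 1.24 ± 0.07. PRG2, a granule protein known from eosinophils, rose by 3.19 ± 0.35.

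For IL-4 in mast cells as labelled, edgeR called 0 genes over 5 donors, with 1543 at an unadjusted p under 0.05. DESeq2 called 198 and limma-voom 4. CISH was at 1.81 ± 0.55 (adjusted p = 0.282, higher in 3 of 5 donors), at 31.1 ± 21.3 CPM with IL-4 and 9.27 ± 4.09 without. IL1RL1 was at -0.56 ± 0.43 (adjusted p = 0.704), IL4R at -0.45 ± 0.22 (adjusted p = 0.502), IL13RA1 at -0.68 ± 0.45 (adjusted p = 0.638) and IL2RG at 0.37 ± 0.49 (adjusted p = 0.845). Of 17 measured STAT6 targets 10 rose adjusted over the list alone and 0 over all genes (list adjusted p = 1.80e-08, and 0.318 with an estimated correlation). MHC class II genes (6 rose adjusted over the list alone), eicosanoid genes (4 rose) and progenitor markers (0) had list adjusted p of 8.32e-09, 0.0104 and 0.0126, and 0.318, 0.342 and 0.853 with an estimated correlation. The MHC class II genes summed to 1080 ± 1550 CPM with IL-4 and 334 ± 124 without (n = 5 donors). In the same libraries monocyte markers were at 622 ± 835 CPM (350 ± 79.2 without), neutrophil markers at 380 ± 612 (177 ± 60.8), T and NK cell markers at 40.6 ± 62.2 (14 ± 7.83) and progenitor markers at 1370 ± 1940 (663 ± 446). The highest sums with IL-4 were 3850, 2110, 1470, 152 and 4830 CPM, and 457, 243, 116, 18 and 597 in the 3 donors that passed the CISH check. The count was 0 to 98 with a donor left out, and 109 without 1 of the 39 libraries.

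In the fit without the 2 donors 3926 genes were called with IL-4, 1834 higher and 2092 lower. MAOA rose by 8.57 ± 0.50, to 552 ± 104 CPM (n = 3 donors). CCL18, a chemokine, rose by 6.91 ± 0.66, CYSLTR2, a leukotriene receptor, by 6.42 ± 0.33, IL17RB by 6.09 ± 0.22 and the transcription factor STAT4 by 5.82 ± 0.33. DNAH2, SLC24A2 and CNR2 rose by 6.28 ± 0.45, 5.87 ± 0.39 and 5.78 ± 0.26. VNN1 and VNN2 fell by 3.15 ± 0.40 and 2.68 ± 0.26, FAIM2 by 2.59 ± 0.20, ARHGAP29 by 2.57 ± 0.14 and SPTB by 2.50 ± 0.12. SLC30A2, GPR112 and CTTN fell by 2.36 ± 0.14, 2.27 ± 0.14 and 2.27 ± 0.22. FCER1A, the IgE-binding chain of the high-affinity receptor, rose by 1.69 ± 0.08, to 549 ± 77.6 CPM, and HDC by 0.82 ± 0.06. LTC4S and PTGER4 rose by 2.23 ± 0.19 and 1.95 ± 0.08, and of 17 eicosanoid genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; list adjusted p = 1.19e-05, and 0.226 with an estimated correlation). CISH rose by 2.71 ± 0.13 and IL2RG by 1.04 ± 0.12, IL4R and IL13RA1 fell by 0.52 ± 0.04 and 1.66 ± 0.25, and IL1RL1 was at 0.14 ± 0.07 (adjusted p = 0.15). Neutrophil markers moved in the same libraries, with 7 of 9 lower (7 adjusted over the list alone; list adjusted p = 4.90e-05, and 0.454 with an estimated correlation). Erythroid and platelet markers, with too few measured for a list test, summed to 252 ± 65.3 CPM with IL-4 and 64.1 ± 30.8 without. Of these sums ITGA2B, the platelet integrin chain, made up 252 ± 65.3 and 63.4 ± 30.7, and it rose by 2.07 ± 0.16.

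IL-13 gave 0 calls in mast cells as labelled over 5 donors, with 933 genes at an unadjusted p under 0.05. DESeq2 called 7 and limma-voom 0. CISH was at 1.35 ± 0.53 (adjusted p = 0.73), higher in 5 of 5 donors. IL1RL1, IL4R, IL13RA1 and IL2RG were at -0.50 ± 0.43, -0.23 ± 0.22, -0.25 ± 0.44 and 0.51 ± 0.49, with adjusted p of 0.777, 0.801, 0.898 and 0.797. MHC class II genes (7 of 12 rose adjusted over the list alone) had a list adjusted p of 7.58e-13, STAT6 targets (0) 1.79e-10, chemokines (0) 0.00792, progenitor markers (0) 0.000414 and monocyte markers (0) 0.036. With an estimated correlation these gave 0.165, 0.19, 0.357, 0.357 and 0.684. With IL-13 the MHC class II genes summed to 1180 ± 1770 CPM (at most 4350), monocyte markers to 695 ± 952 (at most 2400), neutrophil markers to 383 ± 511 (at most 1290) and T and NK cell markers to 47.3 ± 78.3 (at most 187). Progenitor markers summed to 1770 ± 2820 CPM (at most 6810, and 612 in the 3 donors that passed the CISH check). The count was 0 to 2 with a donor left out, and 3 without 1 of the 39 libraries.

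For IL-13 the fit without the 2 donors called 326 genes, 238 higher and 88 lower. CCL18 rose by 6.66 ± 0.68, MAOA by 5.85 ± 0.50, CD209, a lectin, by 5.04 ± 0.44, MRC1, the mannose receptor, by 3.72 ± 0.12 and STAT4 by 3.53 ± 0.37. F13A1, TGFBI and CLEC4A rose by 3.34 ± 0.30, 3.16 ± 0.10 and 2.18 ± 0.19. SPARC fell by 1.21 ± 0.18, LRRN1 by 1.01 ± 0.16, CD36 by 0.87 ± 0.19 and FN1, fibronectin, by 0.81 ± 0.17. ARHGAP29, SPTB, HSPA2 and PLXNA1 fell by 0.81 ± 0.12, 0.78 ± 0.11, 0.73 ± 0.14 and 0.65 ± 0.11. Of 17 STAT6 targets 14 rose (15 adjusted over the list alone, where 1 fell; list adjusted p = 3.73e-27, and 0.00877 with an estimated correlation). CISH rose by 1.54 ± 0.14, while IL1RL1, IL4R, IL13RA1 and IL2RG did not pass, with adjusted p of 0.525, 0.298, 0.118 and 0.137. Cell cycle genes summed to 694 ± 407 CPM with IL-13 and 884 ± 394 without (n = 3 donors). Neutrophil markers summed to 153 ± 51.6 and 186 ± 64.8 CPM.

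**Figure D2:**
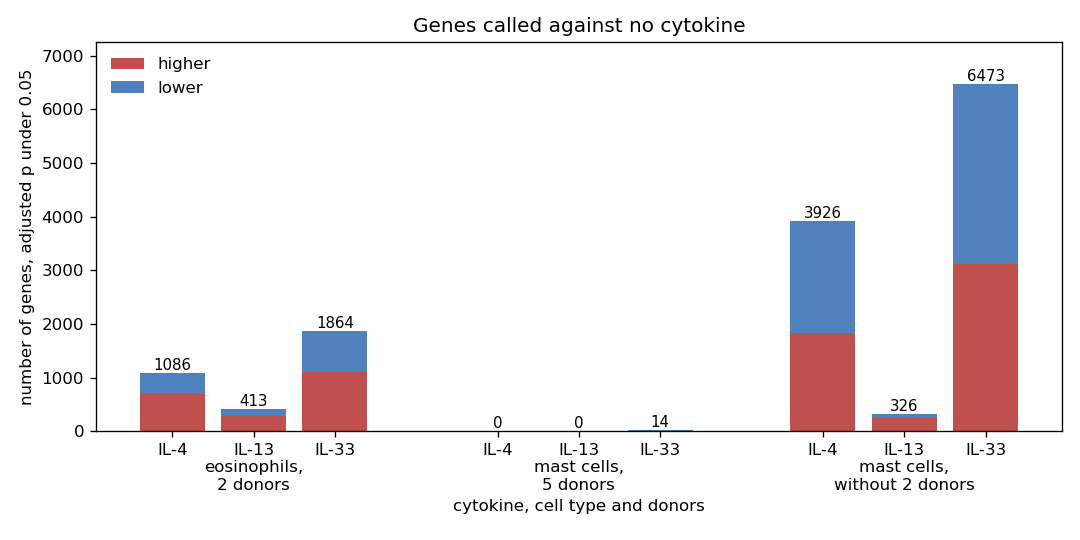
Number of genes called by edgeR (vertical axis, adjusted p under 0.05) for each cytokine against no cytokine, split into higher and lower, in eosinophils of 2 donors, in mast cells of all 5 donors and in mast cells without the 2 donors that did not pass the CISH check. With IL-33 the counts were 1864, 14 and 6473.

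IL-4 and IL-13 were compared directly in eosinophils, and 114 genes differed, 58 higher with IL-4 and 56 lower. CHDH, choline dehydrogenase, was higher with IL-4 by 2.68 ± 0.19 (adjusted p = 2.77e-06), at 53.8 ± 25.6 CPM against 8.71 ± 5.57. DACT1, MAL and TDRD9 were higher by 3.08 ± 0.48, 2.67 ± 0.29 and 1.84 ± 0.29. CAMP, the neutrophil antimicrobial peptide cathelicidin, was lower by -1.57 ± 0.14 (adjusted p = 2.61e-05), and TRPM3, TGM3 and BPIFB1 by -1.49 ± 0.29, -1.43 ± 0.23 and -1.38 ± 0.29. CISH, IL1RL1, IL4R, IL13RA1 and IL2RG did not pass, with adjusted p of 0.182, 0.0926, 0.17, 0.361 and 0.603. The count depended on the scaling, with 31 higher and 9 lower by library totals and 59 and 102 by upper quartile. Without the replicate block edgeR called 0, with 118 at an unadjusted p under 0.05. Leaving out a single library moved the count by over 1.5 times for 16 of 24 libraries. It was 54 and 66 without the untreated libraries 1-3 and 2-2, and 51, 47, 780 and 198 without the IL-4 libraries 1-4, 2-4, 2-5 and 2-6. It was 41, 27, 55, 578, 44 and 382 without the IL-13 libraries 1-7, 1-8, 1-9, 2-7, 2-8 and 2-9. Without the IL-33 libraries 1-10, 1-11, 1-12 and 2-11 it was 56, 67, 228 and 75.

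IL-33 against IL-4 differed in 2411 eosinophil genes (1249 higher with IL-33, 1162 lower), and IL-33 against IL-13 in 2861 (1457 and 1404). COL13A1 and KCNN1 were higher with IL-33 than with IL-4 by 10.37 ± 0.86 and 8.65 ± 0.79, and than with IL-13 by 9.95 ± 0.87 and 8.13 ± 0.80. FFAR1 had 637 counts with IL-33, 1 with IL-4 (CPM ratio 918, 164 to 36303) and 0 with IL-13 (at least 178-fold higher). SLC18A1 had 569, 3 and 1 counts, ratios of 273 (93.0 to 1329) and 478 (85.5 to 18914). CCL26 had 0 counts with IL-33, at least 630-fold lower than with IL-4 and at least 415-fold lower than with IL-13. CCL17 had 1 count with IL-33, and its CPM was higher with IL-4 by a ratio of 1729 (310 to 68322) and with IL-13 by 1778 (319 to 70285). VSTM2L and TGM2, transglutaminase 2, were lower with IL-33 by -6.42 ± 0.27 and -6.29 ± 0.84 against IL-4 and by -6.32 ± 0.27 and -5.83 ± 0.83 against IL-13. IL13RA1 was higher with IL-33 by 1.90 ± 0.14 and 2.12 ± 0.14, and IL2RG by 1.80 ± 0.14 and 1.94 ± 0.14, against IL-4 and IL-13. CISH was lower by -2.05 ± 0.19 and -1.57 ± 0.19. IL1RL1 and IL4R were lower than with IL-4 by -0.58 ± 0.13 and -0.43 ± 0.12, and did not differ past the threshold from IL-13 (adjusted p = 0.701 and 0.584). By library totals the splits were 993 higher and 1508 lower, and 1141 and 1732. By upper quartile the second was 1164 and 2024. Without the replicate block the counts were 126 and 98.

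Between cytokines in mast cells of all 5 donors edgeR called 0 genes in each direct comparison. For IL-4 against IL-13, 420 genes had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. For IL-33 against IL-4 the unadjusted number was 2625, with 693 called by DESeq2 and 6 by limma-voom. For IL-33 against IL-13 these were 1552, 105 and 2. Without the 2 donors, 1604, 6358 and 6091 genes were called. In those 3 donors CYSLTR2, CNR2, MAOA and TGM2 were higher with IL-4 than with IL-13 by 2.93 ± 0.22, 2.81 ± 0.19, 2.72 ± 0.33 and 2.65 ± 0.24. MGAM, SLC30A2, ARHGAP29 and VNN2 were lower by -1.79 ± 0.20, -1.79 ± 0.15, -1.76 ± 0.14 and -1.73 ± 0.27. EBI3, CDH13 and MUC4 had 0 counts with IL-4 and with IL-13, and IL-33 was higher by at least 715-fold, 297-fold and 262-fold against IL-4 and 685-fold, 284-fold and 251-fold against IL-13. FCRL5 was at least 318-fold higher with IL-33 than with IL-4, and IL13 had 1 count with IL-13 against 2185 with IL-33 (CPM ratio 2051, 368 to 81034). NPTX1, SLC24A2, CAMK2B and CLNK were lower with IL-33 than with IL-4 by -6.60 ± 0.36, -4.63 ± 0.34, -4.60 ± 0.20 and -4.27 ± 0.37. CCL18, GATA3, a transcription factor of type 2 immunity, ANXA8 and MAS1L were lower with IL-33 than with IL-13 by -3.57 ± 0.47, -3.44 ± 0.16, -3.24 ± 0.21 and -3.23 ± 0.26. For IL-33 against IL-4, library totals gave 3871 higher and 2623 lower, and TMM 3109 and 3249.

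The overlap of responses was counted for cytokines measured against the same untreated libraries. In eosinophils 261 genes rose and 102 fell with both IL-4 and IL-13, and 0 went opposite ways. Independent lists would share 11.5 and 2.7. Simulated unchanged groups against the same controls shared at most 1 and 2 in 10 simulations, where few genes could be called. These 2 numbers therefore do not show what shared controls add among called genes. With the untreated libraries split between the comparisons, 198 rose and 65 fell in both. The covariance of the log2 changes was 0.207, against 0.051 simulated. IL-4 and IL-33 shared 147 rising and 79 falling genes (43.7 and 16.6 for independent lists, 93 and 47 with split controls), while 99 went opposite ways. IL-13 and IL-33 shared 71 and 28 (17.9 and 5.4, 39 and 7 with split controls), with 57 opposite. Their covariances were 0.124 and 0.0787, against 0.0507 and 0.0511 simulated. In mast cells of all 5 donors 0 calls were shared, which follows from the 0 calls with IL-4 and with IL-13. The covariances there were 0.114 for IL-4 and IL-13, 0.105 for IL-4 and IL-33 and 0.15 for IL-13 and IL-33. Simulated unchanged groups gave 0.0456, 0.0465 and 0.046. The correlations were 0.7, 0.41 and 0.67, against 0.48, 0.5 and 0.49 simulated. In the 3 other donors IL-4 and IL-13 shared 237 rising and 85 falling genes (29.4 and 12.4 for independent lists, 207 and 57 with split controls), with 0 opposite, and a covariance of 0.183 against 0.0224 simulated. IL-4 and IL-33 shared 756 and 1171 (386.3 and 472.3, 637 and 976 with split controls), with 592 opposite. For genes that went opposite ways no number for independent lists was computed. Whether those counts stand above or below it is thus not shown, in either cell type.

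The difference between the cytokine responses of the cell types was tested as an interaction over all donors as labelled. Treatment time, tissue of origin and donors differed with the cell type. So did the code that opens the names of the count columns, which may mark a sequencing batch. These cannot be told apart here. LY75-CD302, CD80 and FFAR1 had 0 to 3 counts in untreated eosinophils, so their fitted differences depend on the prior count and are no bound. With IL-4, 210 of 18157 genes differed, 33 with the higher change in mast cells. GOLM1 changed by 5.96 in eosinophils and 0.03 in mast cells, a difference of -5.99 ± 0.31 (adjusted p = 3.82e-09). GGT5 and ZNF703 differed by -6.05 ± 1.22 and -5.30 ± 1.04. LY75-CD302, a read-through transcript whose reads overlap its parent genes, differed by -11.57 ± 2.17 and is uncertain. OASL and IFI6, interferon-stimulated genes, differed by 2.90 ± 0.63 and 2.77 ± 0.64, and MFSD12 and ARHGEF35 by 2.58 ± 0.57 and 2.29 ± 0.53. OASL stood at 0.227 CPM against 0.047 in mast cells and at 24.7 against 44.3 in eosinophils. IFI6, ARHGEF35 and LY75-CD302 passed in neither cell type alone (adjusted p = 0.335, 0.234 and 0.914 in mast cells and 0.405, 0.0986 and 0.107 in eosinophils). Over the alternatives the IFI6 difference was 1.48 to 4.03, with an adjusted p of up to 0.456. With IL-13, 10 genes differed, 1 higher in mast cells. HMG20B differed by 1.10 ± 0.15, and CD80, GOLM1, VSTM2L and MAT2A by -4.55 ± 0.66, -4.52 ± 0.30, -4.09 ± 0.47 and -2.20 ± 0.30. With IL-33, 530 genes differed, 176 higher in mast cells. CD80, a costimulatory molecule, differed by -7.72 ± 0.56 (adjusted p = 5.50e-07), with 3.16 CPM against 0.0118 in eosinophils and 6.16 against 6.01 in mast cells. FFAR1, COL13A1 and PPM1N differed by -7.41 ± 1.30, -7.27 ± 1.83 and -6.05 ± 0.51, and MIAT, FBP1, CD96 and MDK by 3.37 ± 0.72, 3.33 ± 0.77, 3.24 ± 0.60 and 2.99 ± 0.56. FBP1 and CD96 stood at 0.828 and 0.803 CPM against 0.103 and 0.123 in mast cells, and at 79.2 and 45.1 against 194 and 76.9 in eosinophils. The FBP1 difference was 0.38 to 4.39 over the alternatives (adjusted p of up to 0.92), with the lowest in the fit without the 2 donors. None of the genes named for a difference passed the edgeR test in mast cells of all 5 donors, where OASL, VSTM2L, FBP1 and FFAR1 had too few counts to be tested. Without the replicate block edgeR called 3, 0 and 62, with 268 at an unadjusted p under 0.05 for IL-13, and without the 2 donors 2400, 248 and 3423. For IL-4 the count was 723, 124, 135 and 114 without the eosinophil libraries none 1-3, IL-13 1-7, IL-13 1-8 and IL-4 2-4. For IL-13 it was 6 without either of the IL-13 libraries 1-7 and 1-8.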

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

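The tests of explanations in this part were chosen after the results were seen, except that the bounds for the eosinophil library of lowest depth were set before their test was run, and the tests of differences between cell types were planned.

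In 2 mast cell donors CISH did not rise in the libraries labelled IL-4, at 0.46 and 0.99 times untreated. Nor did BIRC3 in those labelled IL-33, at 0.05 and 0.93 times. CISH reached 3.53 and 2.76 times in libraries labelled IL-13 and IL-33. NF-kB targets summed to up to 2380 CPM in untreated and 3600 CPM in IL-13-labelled libraries, against at most 732 and 691 in the other donors. For 1 of the 2 donors these ratios rest on its only untreated library, that of 201.5 M counts. A fault of that library as the reference was not tested. A lower share of mast cells was weighed by 29 genes that IL-4 raised at least 4-fold in the other donors, since other cells can only add transcripts. In libraries labelled IL-4, 28 and 13 of them stood below 0.5 times the lower of the levels of the granule and IgE receptor genes. The 0 in each other donor largely follows from choosing the genes in those donors, and the 2 donors were chosen for a low IL-4 response. The list levels were 0.89 and 1.05 times the lowest of the other donors for granule genes and 0.47 and 0.99 times for IgE receptor genes. By a stricter bound, the upper quartile, the 29 genes reached 0.81 times in 1 donor. Other values went with a lower share. Monocyte markers reached 2110 CPM against 243 and progenitor markers 4830 against 597. Eicosanoid genes were as low as 3850 CPM against at least 13300, and IL1RL1 changed by -2.24 in 1 donor. The count of genes therefore does not decide on a lower share, which stays open. Of the 8 sums of these donors, 2 correlated best with their own label, at r of at most 0.18, and 2, both from 1 donor, correlated best with another treatment at r of at least 0.3, whereas the 12 sums of the other donors each correlated best with their own label, at r of 0.69 to 0.92. Libraries under another label may account for the pattern in that 1 donor, where the highest r of 0.44 and the CISH values of 3.53 and 2.76 go against cells that did not respond, and both explanations stay open in the other donor, where no correlation with a response passed 0.21; a biological difference between donors was not tested.

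In eosinophils the monocyte genes were lower with IL-4, with IL-13 and with IL-33. Fewer monocytes among the cells would lower their markers by a common amount if no other cell held these transcripts. The 7 markers with enough counts moved apart. Cochran Q was 102.3 for IL-4, 87.1 for IL-13 and 24.8 for IL-33, against a critical value of 22.5 at 0.001. The common log2 change was -0.61, -0.45 and -0.44. Neutrophil markers summed to 8460 ± 4120 CPM in untreated libraries, and whether other cells supplied part of the monocyte markers was not tested. The spread therefore does not decide on a smaller monocyte share. A change of transcription within monocytes or within eosinophils remains a hypothesis that may account for the lower levels, and was not tested.

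The number of eosinophil genes that differed between IL-4 and IL-13 moved with single libraries. The library of lowest depth, IL-13 1-9, may account for much of this, since in the fit without it, which called 55, only 1 of the other 23 libraries moved the count by over 1.5 times, within 27 to 71. In the fits without IL-13 1-7 and 1-8, compared afterwards, 15 and 7 of 23 did so. Library 1-9 differed from these by a chi-square per degree of freedom of 90.36 and 89.28, against 2.04 between them, and whether its depth or another property matters stays open. Many genes stood close to the threshold, with 2504 at an adjusted p of 0.05 to 0.2 against 114 under 0.05, which is consistent with a count that small changes in the spread may move; no biological explanation was tested.

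In 69 groups of libraries or donors searched for 1 value far from the rest, 7 were found. Chance gives about 1 in 20 among independent values. The 40 groups of libraries held several libraries of the same donor, so that rate does not hold for them. Mitochondrial transcripts made up 2% of counts in the eosinophil library IL-13 1-9, against 3.6% to 3.8% in the other 5. One untreated mast cell library held 201.5 M counts, against 12.7 to 15.5 M in the other 8, and 20209 genes with a count, against 16628 to 17445. Among the 5 mast cell donors, 1 value stood apart in each of 4 log2 changes. These were MCU with IL-33 at -0.10 (others -0.54 to -0.48) and IL1RL1 with IL-4 at -2.24 (-0.03 to 0.16). The others were IL1RL1 with IL-13 at -2.22 (0.05 to 0.28) and IL4R with IL-13 at -0.52 (-0.20 to -0.09). The values of IL1RL1 and IL4R came from donors that did not pass the CISH check.

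The naming rule took 21 pairs of a gene and a cytokine from those past the edgeR interaction test between mast cells and eosinophils. The number 21 is thus set by that rule. In all, 210, 10 and 530 genes passed with IL-4, IL-13 and IL-33. Values are the log2 change in mast cells minus that in eosinophils. With IL-4 they were 2.90 for OASL, 2.77 for IFI6, 2.58 for MFSD12 and 2.29 for ARHGEF35, and -6.05 for GGT5, -5.99 for GOLM1 and -5.30 for ZNF703. LY75-CD302, at -11.57, had 0 counts in untreated eosinophils, so this fitted value is no bound. With IL-13 HMG20B was at 1.10, CD80 at -4.55, GOLM1 at -4.52, VSTM2L at -4.09 and MAT2A at -2.20. With IL-33 MIAT, FBP1, CD96 and MDK were at 3.37, 3.33, 3.24 and 2.99, and COL13A1 and PPM1N at -7.27 and -6.05. FBP1, at 0.828 CPM against 0.103 in mast cells, was at 0.38 without the 2 donors (adjusted p = 0.865), and over the alternatives at 0.38 to 4.39 with an adjusted p of up to 0.92. IFI6 was at 1.48 to 4.03 over the alternatives, with an adjusted p of up to 0.456. CD80 at -7.72 and FFAR1 at -7.41 had 1 and 2 untreated eosinophil counts, so their fitted values depend on the prior count.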

How the results depend on the processing

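The alternatives here were planned, except the fits without the 2 mast cell donors that did not pass the CISH check and with the deepest library thinned, which were chosen after seeing the data. Counts are genes called by edgeR unless another tool is named. Where a count moved by over 1.5 times the cause was not tested, apart from the tests above for IL-4 against IL-13 in eosinophils. Of 5953 values of named eosinophil genes, each under at most 36 alternative settings, 5726 kept their direction and side of the threshold, 218 lost the call, 8 gained it and 1 reversed. Of 342 values of list tests, by camera with an estimated correlation or by fry, 245 kept theirs, 83 lost it and 14 gained it. With an estimated correlation no list passed in eosinophils or in mast cells of all donors. The lowest adjusted p there were 0.164 and 0.165. In the 3 remaining donors STAT6 targets with IL-13, and NF-kB targets and receptor chains with IL-33, still passed. By fry, STAT6 targets with IL-4 kept the call in eosinophils (adjusted p = 0.00298) and lost it in mast cells of all donors (0.079). Of 1622 values of genes in all mast cell donors 1526 kept theirs, 48 lost it, 34 gained it and 14 reversed. In the 3 remaining donors 1768 of 1869 kept theirs, 78 lost it, 22 gained it and 1 reversed. Of 1696 values of differences between cell types 1595 kept theirs and 101 lost it. Depth limits genes of few counts most, and 2 eosinophil donors leave 3 residual degrees of freedom.

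In mast cells of all donors, DESeq2 called 198 genes with IL-4, 7 with IL-13, 1580 with IL-33, 693 for IL-33 against IL-4 and 105 for IL-33 against IL-13. Limma-voom called 4 with IL-4, 106 with IL-33, 6 for IL-33 against IL-4 and 2 for IL-33 against IL-13. With every library as a sample the counts were 1836, 787 and 4299 for IL-4, IL-13 and IL-33, and 57, 3212 and 1590 for IL-4 against IL-13, IL-33 against IL-4 and IL-33 against IL-13. Leaving out the 2 donors gave 3926, 326, 6473, 1604, 6358 and 6091 in the same order. For IL-33, library totals gave 23 and the thinned library 159. Only the 2 treatments compared gave 0 for IL-33 (2251 at an unadjusted p under 0.05) and 1 for IL-4 against IL-13. With 1 donor left out the counts were 0 to 98 for IL-4, 0 to 2 for IL-13, 0 to 3503 for IL-33, 0 to 3345 for IL-33 against IL-4 and 0 to 2093 for IL-33 against IL-13. With 1 library left out they were 0 to 109, 0 to 3 and 9 to 593 for IL-4, IL-13 and IL-33, and 0 in the direct comparisons.

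For IL-4 against IL-13 in eosinophils, library totals gave 40, no low-count filter 896, the filter at 5 CPM 34, DESeq2 486 and limma-voom 269. Every library as a sample gave 2640, 829 and 3220 for IL-4, IL-13 and IL-33, 1573 for IL-4 against IL-13 and 4878 for IL-33 against IL-13. Only the 2 treatments compared, also with libraries as samples, gave 4565 for IL-4, 3974 for IL-33 and 4437 for IL-33 against IL-4. With 1 donor left out the counts were 558 to 5218, 200 to 1563 and 779 to 6390 for IL-4, IL-13 and IL-33, and 38 to 158, 1445 to 4790 and 1238 to 5755 for IL-4 against IL-13, IL-33 against IL-4 and IL-33 against IL-13. With 1 library left out they were 720 to 1382, 304 to 503, 1398 to 2076, 27 to 780, 1869 to 2603 and 2133 to 3413 in that order. With split untreated libraries the shared genes that fell with IL-4 and IL-13 were 65, those with IL-4 and IL-33 were 93 rising and 47 falling, and those with IL-13 and IL-33 were 39 and 7. Upper quartile scaling moved the median log2 change of all genes for IL-33 against IL-13 to -0.116 (-0.019 with TMM), and library totals moved that for IL-33 against IL-4 to -0.111 (-0.016).

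Without the donor as a replicate block, the eosinophil counts were 0, 0 and 59 for IL-4, IL-13 and IL-33, and 0, 126 and 98 for IL-4 against IL-13, IL-33 against IL-4 and IL-33 against IL-13. The counts of 0 had 602, 367 and 118 genes at an unadjusted p under 0.05. In mast cells of all donors the count for IL-33 was 0 (1300 unadjusted), and the other 5 comparisons called 0 with and without the block. With the 2 donors left out, the fit with no block called 976, 27 and 2957 genes for IL-4, IL-13 and IL-33, and 150, 2907 and 2653 for the direct comparisons in the same order. For the differences between cell types it called 3, 0 (268 unadjusted) and 62.

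For the differences between cell types, library totals gave 354 for IL-4, and DESeq2 721, 81 and 1180 for IL-4, IL-13 and IL-33. Limma-voom gave 17 for IL-13, every library as a sample 2528, 726 and 3224, and the fit without the 2 donors 2400, 248 and 3423. With 1 donor left out they were 57 to 745, 4 to 94 and 118 to 1507, and with 1 library left out 114 to 723, 6 to 15 and 449 to 756.

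The reversed genes passed the threshold in none of these fits. IL2RG with IL-13 in eosinophils went from -0.04 to 0.00 without donor 2, and lay at -0.07 or above with any donor or library left out. In mast cells IL13RA1 with IL-13 went from -0.25 to 0.24 by limma-voom, to 0.09 without the replicate block and within -0.66 to 0.01 with a donor or library left out. IL13RA1 with IL-33 went from 0.06 to -0.02 and -0.16 with a donor left out (0.32 at most), to -0.03 with a library left out and to -0.27 without the 2 donors, and in that fit to 0.01 with a further donor left out. IL1RL1 with IL-13 went from -0.50 to within -0.71 to 0.15 with a donor or library left out and to 0.11 without the 2 donors. IL1RL1 with IL-4 went from -0.56 to within -0.74 to 0.09, and to 0.14. AURKB with IL-4 went from -0.22 to 0.15 by limma-voom and to 0.10 without the replicate block, where MCM6 went from -0.14 to 0.06.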

Other observations

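The splits of the samples and the values without the 2 mast cell donors below were chosen after seeing the data.

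In eosinophils CD200R1, an inhibitory receptor of myeloid cells, rose with each cytokine, by 2.16 ± 0.19 with IL-4, 1.36 ± 0.19 with IL-13 and 1.09 ± 0.19 with IL-33 (edgeR adjusted p = 1.77e-06, 0.000454 and 0.000904). CYSLTR2, a receptor for cysteinyl leukotrienes, went both ways. It rose by 1.26 ± 0.26 with IL-4 and 1.29 ± 0.26 with IL-13 and fell by 1.02 ± 0.27 with IL-33 (adjusted p = 0.0183, 0.0361 and 0.0422). CD80 went from 1 untreated count to 277 with IL-33, a CPM ratio of 256 (45.6 to 10151), and CSF2, which encodes GM-CSF, from 2 to 70, a ratio of 32.4 (8.63 to 272).

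In mast cells of all 5 donors none of 18 cell cycle genes passed the edgeR test with IL-4 or IL-33, over all genes or adjusted over the list alone, and the lowest unadjusted p were 0.299 and 0.0842. The list adjusted p was 0.48 and 0.737, and 0.935 and 0.964 with an estimated correlation. MCM6, part of the replicative helicase, was at -0.14 ± 0.18 with IL-4 (adjusted p = 0.835), and AURKB, a mitotic kinase, at -0.22 ± 0.31 with IL-4 and -0.58 ± 0.31 with IL-33 (adjusted p = 0.859 and 0.288). PLA2G4A, the phospholipase that releases arachidonic acid, was at 1.31 ± 0.50 with IL-33 (adjusted p = 0.144), and CSF2 at 4.08 ± 1.53 with IL-4 (adjusted p = 0.369). In the fit without the 2 donors, 11 of the 18 cell cycle genes fell with IL-4 (16 adjusted over the list alone; list adjusted p = 5.26e-06, and 0.65 with an estimated correlation), MCM6 by 0.44 ± 0.06 and AURKB by 0.63 ± 0.13. With IL-33 9 of 18 fell (9 adjusted over the list alone; list adjusted p = 0.00696, and 0.619 with an estimated correlation), AURKB by 1.13 ± 0.13. PLA2G4A rose with IL-33 by 2.29 ± 0.12, to 283 ± 58.0 CPM, and CSF2 went from 2 untreated counts to 341 with IL-4, a CPM ratio of 170 (46.7 to 1409).

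Other splits of the mast cell sums into groups of the same sizes were fitted, 60 of 126 per comparison with all donors. For IL-33 against no cytokine, 3 of the 60 splits, the real one included, called at least the real 14 genes, and the highest other split called 501, so chance is not excluded. In the other 5 comparisons edgeR called 0 genes, so all 60 of 60 splits called as many. The highest other split called 262 for IL-4, 0 for IL-13, 0 for IL-4 against IL-13, 191 for IL-33 against IL-4 and 1843 for IL-33 against IL-13. The splits with 262, 501 and 1843 calls part only 3 of the 5 donor pairs, while the real ones part every pair. Among the other drawn splits that part every pair, the highest called 0 for IL-4 (5 splits), 0 for IL-13 (7), 1 for IL-33 (8), 0 for IL-4 against IL-13 (6), 191 for IL-33 against IL-4 (8) and 0 for IL-33 against IL-13 (6). Splits that call many times the real number point to a structure of the samples, which was not tested. With 3 donors there are 10 splits per comparison, too few for a share under 0.05. In each of the 6 comparisons 1 of the 10, the real one, called as many as it, and the highest other called 0. Eosinophils had 2 donors per group, so no other splits were drawn.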
